A study of Mus musculus with 6 samples.

How the data were processed

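The series measured RNA in THY1-positive spermatogonia, testicular germ cells enriched by a surface protein, from Ddx20 knockout mice and from control littermates. Each of the 6 libraries came from about 1000 cells at day 4, with 3 control and 3 knockout libraries. Per the labels' protocols, RNA was reverse transcribed with an anchored oligo-dT primer, amplified by PCR with SMART-seq2 and sequenced as paired reads of 150 bp on an Illumina instrument. SMART-seq2 amplifies whole cDNA, adds no molecular identifiers and keeps no record of the strand. Copies of 1 molecule made by PCR can therefore be counted more than once, and intervals and floors cover counting error only.

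The authors deposited read counts per Ensembl gene for the 6 libraries. Per the submitters' processing notes, the genome build was mm10 and the tools were Trimmomatic 0.39, STAR 2.7.5c, StringTie 2.1.7, DESeq2 and edgeR, with no roles given. The counter, the annotation release, the strand setting and the filter behind the table are not given in the sources used here. The deposited counts are whole numbers, and each of the 22579 genes listed has at least 1 read over the 6 libraries. A further column of the deposited table equals the sum of the counts of the 6 libraries in all 22579 genes. That column and the authors' column of mean values over the libraries were not used in any test. Reads shared by near-identical genes, such as ribosomal protein genes and their pseudogenes, histone genes, actin genes and the Pramef family, can have been split or dropped by the counting. Reads of overlapping genes on opposite strands cannot be told apart without a strand setting.

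Gene symbols, positions, exon lengths and GC content were taken from GENCODE M21 on GRCm38, which is the mm10 assembly, and 22562 of the 22579 gene identifiers matched. Depth ranged from 8428871 to 12497967 counted reads per library. Each pair of libraries was compared by a chi-square statistic per gene over genes with at least 20 reads in the pair, where sampling noise alone gives 1.

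The main test, fixed before the data were examined, was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with robust dispersion, TMM scaling, the filter filterByExpr and genotype as the sole term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and 14766 genes were tested. Standard errors of log2 fold changes were obtained as the fold change over the square root of F. Expression is given as CPM, counts scaled to TMM-adjusted library size, as mean ± SD over 3 libraries. Genes without a read in the controls, olfactory receptor genes and the floor of 3 counts are the exception. Their CPM, and folds against that floor, are relative to total counts without TMM scaling. All p-values are two-sided. The labels describe littermates but do not say which library came from which animal or litter, so p-values measure only the spread between these samples, which may be technical.

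In all, 28 gene lists were fixed before the data were examined, among them germ cell stages, cell cycle, p53, stress response, the SMN complex, splicing, ribosome, energy metabolism, 2 quality lists and 8 lists of other cell types. Ddx20 was left out of every list. The 27 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and a list was called at a Benjamini-Hochberg adjusted p under 0.05 over the 27 lists. Camera compares a list with all other genes. The test was repeated with a correlation estimated from the data, and fry asked whether a list moved on balance in 1 direction.

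Genes named in the text were Ddx20, then the 10 higher and 10 lower called genes with the largest absolute log2 fold change among those with an absolute value of at least 1, groups that did not overlap and a mean of at least 10 CPM in the higher group. Predicted genes, clone names, pseudogenes and mitochondrially encoded genes were left out of that choice. From each called list and each cell type list, up to 4 members with the smallest p were added, and lists with 5 or fewer called members are named in full. Other names are marked as chosen after their values were seen.

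Alternatives fixed at the same time were DESeq2 size factors, library size alone, other filters on low counts, the replicate number as a block, each library left out, mitochondrially encoded genes left out, the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights and an edgeR test against a log2 fold change of 1. Counting knockout 1 and knockout 2 as 1 library (their rounded mean) and removing a lowess trend of each library with exon length and GC content (span 0.3) were chosen after seeing the data. So were 2 gene lists, of which the list on ERK signalling is given and the other is not reported here.

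The tests were tried on simulated data for the comparison of knockout with control, with the real control means and library sizes. Each of 5 simulations held 200 changed genes, drawn only from genes at 5 CPM or more in controls. The recovery rates therefore do not cover genes under that level. The simulated spread between libraries was the same in both groups, whereas the real controls were more variable. The coefficient of variation beyond counting noise, 1 value for all genes, was 0.433 for the 3 controls. It was 0.282 for knockout 1 and 3 and 0.0369 for knockout 1 and 2. The shares of false calls do not cover such unequal spread. With independent libraries (14023 genes on average), edgeR recovered 36.6% of genes changed by 1 on the log2 scale and 87.4% of those changed by 2, and 5.92% of its calls were false. When knockout 1 and 2 shared 1 biological draw, 15.1% of the calls from 6 libraries were false, against 5.02% with the pair counted as 1 library, which recovered 25.2% and 80.8%. In that second setting 20.5% of DESeq2 calls and 3.96% of limma-voom calls were false, against 19.2% and 3.57% with independent libraries. Camera called a list of 60 genes lowered by 0.5 in 5 of 5 simulations with independent libraries and 0 of 100 random lists. With the shared draw fitted as 6 libraries it called the changed list in 5 of 5 and 1 of 100 random lists, and the changed list in 4 of 5 with an estimated correlation. The simulated noise was independent between genes, whereas the estimated correlation in the real lists reached 0.801. These simulations therefore do not show how often camera calls lists of correlated genes falsely.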

Results

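RNA was counted in 6 libraries of about 1000 THY1-positive spermatogonia each, taken at day 4 from 3 control samples and 3 samples of Ddx20 knockout mice. The labels also shorten the knockout to cKO, the usual short form of conditional knockout, without naming the cells in which the gene was deleted. THY1 is a surface protein used to enrich undifferentiated spermatogonia, the germ cell population that holds the spermatogonial stem cells. DDX20, also called Gemin3, is a DEAD-box RNA helicase and a member of the SMN complex, which assembles spliceosomal ribonucleoproteins. The series asks how the transcriptome of these cells differs when Ddx20 is lost. Total counts were 8428871, 11035515 and 11893287 in the controls and 11656130, 11904762 and 12497967 in the knockouts.

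Ddx20 itself was lower in each knockout library than in each control library. Its gene (ENSMUSG00000027905) lies on chromosome 3 at 105678270 to 105687574 of mm10, on the minus strand. The 3 controls held 668, 383 and 531 reads and the 3 knockouts 128, 168 and 119. Normalized expression was 47.0 ± 14.8 CPM (SD, n = 3) in controls and 12.6 ± 2.35 CPM (SD, n = 3) in knockouts, which is 3.72-fold lower. The log2 fold change was −1.89 ± 0.26 (SE), with an adjusted p of 0.0118 and an unadjusted p of 1.79e-05 by the edgeR quasi-likelihood test. Reads from exons outside the deleted part, which the labels do not give, and from other cells still count towards the remaining level. With the edgeR test the adjusted p was 0.0541 with knockout 1 and 2 counted as 1 library, 0.0554 without knockout 1 and 0.0620 without knockout 3. With that pair as 1 library it was 1.43e-05 by DESeq2 and 0.00105 by limma-voom.

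The libraries also differed in composition. Mitochondrially encoded transcripts took 14.6%, 16.9% and 14.0% of reads in the controls and 19.8%, 19.8% and 20.1% in the knockouts. After thinning to equal depth, 16822, 17860 and 17284 genes had a read in the controls, against 18780, 18820 and 18972 in the knockouts. Knockout 1 and knockout 2 were much closer to each other than any other pair. Their mean chi-square per gene was 1.779, where sampling noise alone gives 1 and the other 14 pairs gave 11.956 to 104. They differed by more than sampling noise and were entered as separate libraries, but PCR reads of 1 preparation can also exceed that noise, so this does not show that they are separate samples. SDs and p-values that treat the 3 knockouts as independent may be too small. For this reason the value with the pair counted as 1 library stands beside the main counts.

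**Figure D1:**
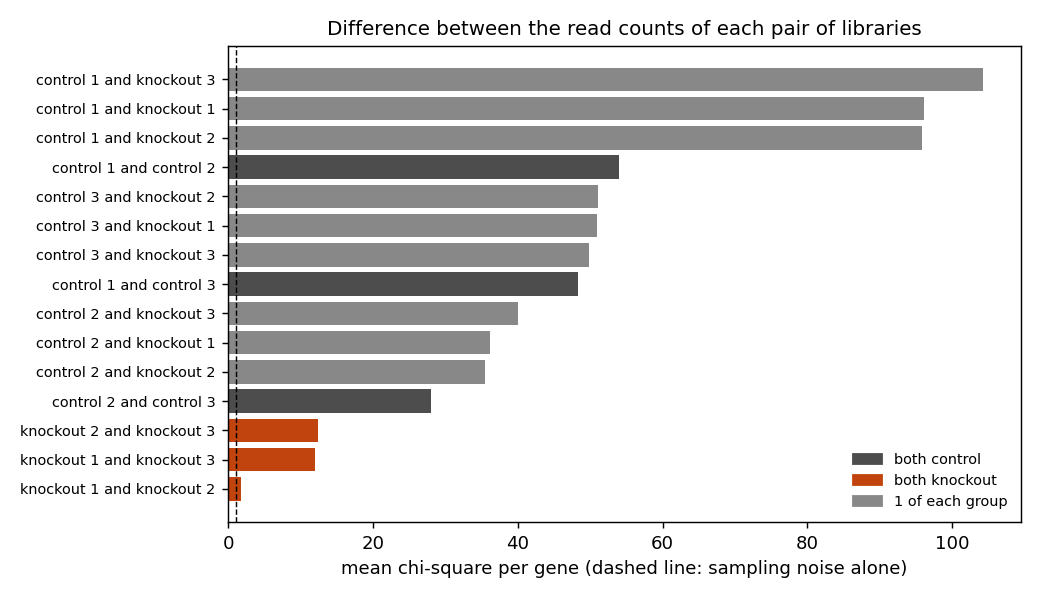
Mean chi-square per gene between the counts of each of the 15 pairs of libraries (horizontal axis, no unit), with pairs of 2 controls in dark grey, pairs of 2 knockouts in orange, mixed pairs in light grey and the dashed line at the value of sampling noise, 1. Knockout 1 and knockout 2 stand at 1.779, and the other pairs lie between 11.956 and 104.

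In the knockouts the lists of stem cell regulators, DNA replication and mitosis genes were lower by camera, and those of ribosomal proteins and of several somatic cell types were higher. None of the lists passed with an estimated correlation (adjusted p = 0.184, 0.0899, 0.116 and 0.405 for the first 4). Of 14766 genes tested, 713 differed between knockout and control by the edgeR test, 300 higher and 413 lower in the knockouts. Among them 353 had an absolute log2 fold change of at least 1, 211 higher and 142 lower. In 4810 genes, 32.6% of those tested, the 2 groups did not overlap, where chance gives 10% for 3 against 3 independent libraries. With knockout 1 and 2 counted as 1 library it was 5274 genes, 35.7%, where chance gives 20%. With knockout 1 and 2 counted as 1 library, edgeR called 1 gene, Cln3, a lysosomal membrane protein gene chosen here after its value was seen (log2 fold change 1.71 with an adjusted p of 0.0314), while 2150 genes had an unadjusted p under 0.05. In that setting DESeq2 called 466 genes and limma-voom 505, of which 401 and 421 were among the 713. Leaving out control 2 gave 182 genes by edgeR, and leaving out knockout 1, 2 or 3 gave 5, 10 and 3. Scaling by library size alone gave 226 higher and 1152 lower genes, so that 83.6% of calls were lower against 57.9% with TMM scaling, because it moved the median log2 fold change of all genes from 0.01 to −0.26. Directions below are relative to TMM scaling.

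Among the genes with the largest decreases, Pim1, a serine/threonine kinase gene induced by cytokine and growth factor signalling (chromosome 17, 29490753 to 29496112), fell from 54.5 ± 5.37 to 17.5 ± 2.55 CPM (SD, n = 3 per group), a log2 fold change of −1.64 ± 0.19 (SE) with an edgeR adjusted p of 0.0101. Lonrf3, which encodes a RING finger protein, fell by 2.30 on the log2 scale, from 34.6 ± 0.646 to 7.03 ± 2.98 CPM. Pramef12, a germ cell gene of a multigene family, fell by 2.15 on the log2 scale, from 48.2 ± 14.1 to 10.9 ± 0.458 CPM. The kinesin gene Kif18b had a log2 fold change of −1.62 and Chtf18, which encodes a subunit of a DNA replication clamp loader, one of −3.11, which was −5.00 without knockout 3 (edgeR adjusted p 0.0568). The others were Zfp384 (log2 fold change −2.79), Brat1 (−2.01), Ttc30a1 (−1.83), Ammecr1 (−1.77) and the cyclin gene Ccng2 (−1.69). Adjusted p values of these 10 genes by edgeR ran from 0.0101 to 0.0402. Pramef12 can share reads with related genes, and Chtf18, Zfp384 and Pim1 overlap exons of genes on the other strand.

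The genes with the largest increases were mostly expressed at a low level in controls. Actg2, a smooth muscle actin gene (chromosome 6, 83512905 to 83536265), rose from 0.962 ± 0.452 to 10.1 ± 3.19 CPM (SD, n = 3 per group), a log2 fold change of 3.35 ± 0.49 (SE) with an edgeR adjusted p of 0.0119. Lmo1, a LIM domain transcription cofactor gene, rose from 2.78 ± 1.21 to 15.0 ± 2.34 CPM. Several genes known from leukocytes were among the 10: Ly6c2 (log2 fold change 2.59), Ctsw (2.04) and the chemokine receptor gene Ccr8 (2.02). The others were Rgs11 (2.31), Zfp280c (2.18), the cytidine deaminase gene Apobec3 (from 2.87 ± 1.14 to 12.3 ± 2.47 CPM), the troponin gene Tnni1 (2.03) and Aspa (2.01). Adjusted p values of these 10 by edgeR ran from 0.0119 to 0.0383. Actg2 and Ly6c2 have close paralogs, and Rgs11, Apobec3 and Ctsw overlap exons of genes on the other strand. Of the 114 genes named under the fixed rule besides Ddx20, 90 were called. None of the 90 was called by edgeR with the pair counted as 1 library, and 53 lost their call without control 2. The number was 86, 85 and 89 without knockout 1, 2 and 3, 11 and 21 without control 1 and 3, and 13 with the replicate block. With the trend with gene length and GC content removed 17 lost their call, among them Utf1 and Fos.

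**Figure D2:**
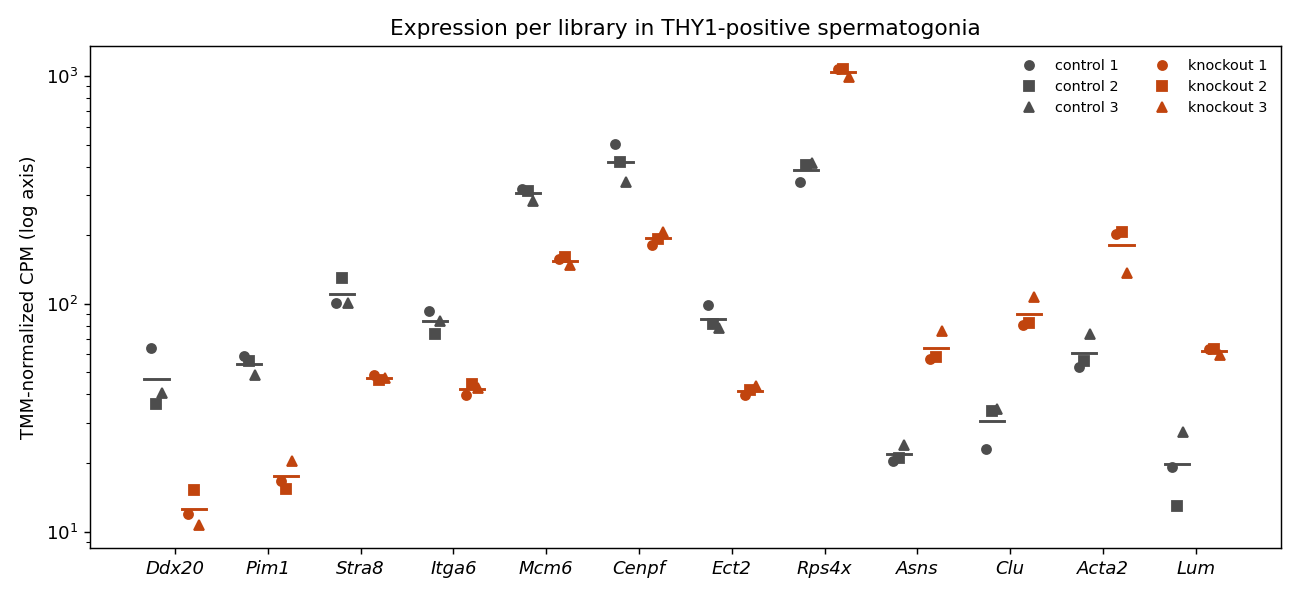
TMM-normalized CPM (log axis) of 12 named genes in each of the 6 libraries, controls in grey and knockouts in orange, with symbols for the replicate numbers and short lines for the group means. The knockout libraries lie below the controls for Ddx20, Pim1, Stra8, Itga6, Mcm6, Cenpf and Ect2 and above them for Rps4x, Asns, Clu, Acta2 and Lum.

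Transcripts of undifferentiated spermatogonia and stem cells were lower as a group. Of 35 tested members 6 fell, 1 rose and 28 did not pass, and 15 fell and 4 rose when adjusted over the list alone. Itga6, an integrin gene of stem cell membranes, fell from 83.9 ± 9.70 to 42.2 ± 2.33 CPM (log2 fold change −0.99). Foxc2, a transcription factor gene, fell by 1.37 on the log2 scale and Tex14, needed for germ cell bridges, by 0.84. The receptor genes for GDNF, the niche factor of these cells, were also among the called members: Gfra1 fell by 0.69 and Ret by 0.67 on the log2 scale, as did the GDNF-responsive gene Etv5 by 0.65, these 3 being chosen after their values were seen. The calls of Gfra1 and Ret were lost with the length and GC trend removed (edgeR adjusted p 0.0510 and 0.0564) and with the pair counted as 1 library (0.223 and 0.237 by edgeR, 0.104 and 0.0974 by DESeq2, 0.0912 and 0.0880 by limma-voom). Their log2 fold changes by edgeR were then −0.58 and −0.54 and −0.64 and −0.61. Utf1, a chromatin factor gene of early spermatogonia, rose by 1.40 on the log2 scale. The list had a median log2 fold change of −0.49 and a camera adjusted p of 0.000451, and adjusted p = 0.184 with an estimated correlation. In the same knockout libraries 6 lists of other cell types were higher by camera (adjusted p 0.131 to 0.405 with an estimated correlation). Mitochondrially encoded transcripts took 19.9% ± 0.194 of reads in knockouts against 15.2% ± 1.54 in controls (SD, n = 3 per group).

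Genes of differentiating spermatogonia moved in both directions. Of 19 tested members 5 fell and 2 rose, against 7 and 4 adjusted over the list alone. Stra8, a retinoic acid target needed for meiotic entry (chromosome 6, 34920163 to 34939344), fell from 111 ± 16.9 to 47.4 ± 1.03 CPM, a log2 fold change of −1.22 ± 0.16 (SE) with an edgeR adjusted p of 0.0101. Kit, the receptor gene that marks differentiation, fell by 1.02 on the log2 scale, the sex determination gene Dmrt1 by 0.84, Mki67 by 0.88 and Uhrf1 by 0.77. Lmo1 and Prss50 rose, with log2 fold changes of 2.44 and 2.78, the latter 2.46 with an edgeR adjusted p of 0.0621 with the length and GC trend removed. The list as a whole did not pass (median −0.05, mean 0.24, camera direction down, adjusted p 0.332 and 0.405 with an estimated correlation), and its median ran from −0.11 without knockout 1 to 0.01 without knockout 3. Names beyond Lmo1 and Stra8 here were chosen after their values were seen.

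Other germ cell lists did not pass. Among 20 germ cell identity genes Mael and Dppa3 rose and Pramef12 fell, with 2 up and 4 down adjusted over the list alone (median −0.08, −0.16 without control 3 or knockout 3 and −0.01 without control 2, mean 0.10, camera direction down, adjusted p 0.332). Dppa3 had 2 reads in all controls together and 86 in the knockouts, a ratio of 37.4 relative to library size with a 95% exact interval of 10.04 to 314 that covers counting error only. Its log2 fold change of 5.20 was 7.89 without control 2, where its call was lost (edgeR adjusted p 0.0509). The germ cell helicase gene Ddx4, chosen after its value was seen, stood at 365 ± 43.7 CPM in controls and 465 ± 18.7 CPM in knockouts, with an edgeR adjusted p of 0.233. Among 22 prospermatogonial and piRNA pathway genes Mael rose and Pld6 fell (log2 fold changes 0.79 and −2.08), with 2 up and 3 down adjusted over the list alone (median 0.02, 0.21 without control 3 and 0.00316 without knockout 3, mean −0.10, camera direction down, adjusted p 0.977). Among 32 meiosis genes Hormad1 and Tex12 rose (0.76 and 0.63) and Stra8 and Sycp1 fell (−1.22 and −0.73), also 2 and 2 adjusted over the list alone (median 0.11, mean 0.09, camera direction down, adjusted p 0.617). Library size scaling turned the medians of the last 2 lists to −0.27 and −0.19, and the meiosis median was −0.13 without control 2 and −0.29 without knockout 3. With the trend with gene length and GC content removed, Mael had an adjusted p of 0.0851, Hormad1 of 0.238 and Tex12 of 0.822.

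DNA replication genes were lower as a list. Of 65 tested G1/S members 16 fell, 0 rose and 49 did not pass, and 23 fell adjusted over the list alone. All 6 subunit genes of the MCM replicative helicase from Mcm2 to Mcm7 were among the 16: Mcm6 fell from 306 ± 19.5 to 155 ± 6.49 CPM (SD, n = 3 per group), a log2 fold change of −0.98 ± 0.15 (SE), and Mcm3, Mcm7 and Mcm4 fell by 0.97, 0.95 and 0.95 on the log2 scale. Mcm2 and Mcm5 fell by 0.73 and 0.71, the last 2 being named after their values were seen. Adjusted p values of the 6 by edgeR ran from 0.0119 to 0.0314. The list median was −0.34, with a camera adjusted p of 8.27e-09, and adjusted p = 0.0899 with an estimated correlation.

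Mitotic genes were also lower as a list. Of 64 tested G2/M members 18 fell, 0 rose and 46 did not pass, and 30 fell and 1 rose adjusted over the list alone. Cenpf, a centromere protein gene (chromosome 1, 189640606 to 189688086), fell from 421 ± 80.0 to 194 ± 12.4 CPM, a log2 fold change of −1.12 ± 0.18 (SE). Ect2, an exchange factor gene for cytokinesis, fell by 1.05 on the log2 scale, the condensin gene Ncapd2 by 0.97 and the contractile ring gene Anln by 0.92. Among members named after their values were seen, Top2a fell by 1.12 and Foxm1, a transcription factor gene of the G2/M programme, by 1.58. The list median was −0.47, with a camera adjusted p of 1.76e-13, and adjusted p = 0.116 with an estimated correlation. G1/S and G2/M transcripts took 0.997% ± 0.0908 and 1.02% ± 0.0627 of reads in controls and 0.677% ± 0.00165 and 0.664% ± 0.0320 in knockouts (SD, n = 3 per group).

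Cyclin-dependent kinase inhibitors and quiescence genes were not higher. Among 22 members Ccng2, Cdkn1b and Foxo3 fell (log2 fold changes −1.69, −1.30 and −0.87), with 2 up and 6 down adjusted over the list alone, and the list did not pass (median −0.27, camera adjusted p 0.0560, 0.368 with an estimated correlation). It passed with the pair counted as 1 library (0.0371), without control 2 (median −0.41, 0.0231), without knockout 1 or 2 (0.0338 and 0.0464), without a filter on low counts (0.0130), with library size scaling (0.0456) and with the length and GC trend removed (0.0177), while without control 1 the median was −0.05 and the adjusted p 0.216. Among 36 p53 targets Sesn2 and Perp rose (2.04 and 1.47), also 2 adjusted over the list alone, while Btg2 and Xpc had log2 fold changes of 0.54 and −0.72 that did not pass. The list passed with a camera adjusted p of 0.0406 and a median of 0.40 (adjusted p = 0.368 with an estimated correlation). Its call was lost with the pair as 1 library (0.0640), without control 1 or 3 (0.168 and 0.0688) and without knockout 1 or 3 (0.0783 and 0.0557). It was also lost with library size scaling (0.0633), with the length and GC trend removed (0.0780), with the replicate block (0.0634) and by fry (0.0507).

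Stress response genes moved in part. Among 29 genes of the integrated stress and unfolded protein responses 3 rose and 1 fell, with 3 up and 2 down adjusted over the list alone. Asns, the asparagine synthetase gene and a target of the transcription factor ATF4, rose from 21.9 ± 1.94 to 63.8 ± 10.3 CPM, a log2 fold change of 1.54 ± 0.19 (SE) with an edgeR adjusted p of 0.0101. Sesn2 rose by 2.04 on the log2 scale. Slc7a3, a cationic amino acid transporter gene, had 0 reads in the 3 controls and 68 in the knockouts, which is at least 19.7-fold higher against a floor of 3 counts over the control group. Pdia4, a chaperone gene of the endoplasmic reticulum, fell by 0.84 on the log2 scale. The list did not pass (median 0.05, camera adjusted p 0.332), its median was the same with Slc7a3 at its bound, and it turned to −0.20 with library size scaling, −0.10 without control 1 and −0.03 without knockout 3.

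For the complex that contains DDX20, no member passed. Of the 25 other genes of the SMN complex and the Sm proteins 0 were called by edgeR, also adjusted over the list alone, while 1 rose and 3 fell at an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 3 (median 0.09, mean 0.00, camera direction down, adjusted p 0.977; the median was −0.19 with library size scaling and −0.02 without control 1). Spliceosome genes were lower as a group: of 61 members 6 fell and 1 rose, against 13 and 2 adjusted over the list alone. The splicing factor genes Srsf2 and Hnrnpu fell by 0.74 and 0.91 on the log2 scale, and the helicase genes Snrnp200 and Dhx15 by 0.80 and 0.73. The median was −0.23, with a camera adjusted p of 0.00800, and adjusted p = 0.257 with an estimated correlation.

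Ribosomal protein transcripts were higher as a list. Of 85 members 7 rose, 0 fell and 78 did not pass, and 23 rose adjusted over the list alone. Rps4x (chromosome X, 102184941 to 102189394) rose from 387 ± 39.2 to 1044 ± 50.8 CPM, a log2 fold change of 1.43 ± 0.18 (SE) with an edgeR adjusted p of 0.0101, and Rpl22l1, Rpl4 and Rpl10 rose by 1.22, 1.08 and 0.97 on the log2 scale. The median was 0.58, with a camera adjusted p of 3.4e-17, and adjusted p = 0.405 with an estimated correlation and 0.105 by fry. Without control 1 the median was 0.38. These genes are short and have many pseudogenes, and shorter genes were higher in the knockouts: the median log2 fold change was 0.34 in the eighth of genes with the shortest exon length and −0.21 in the eighth with the longest. With the trend with length and GC content removed, the ribosomal protein median was 0.33 and the camera adjusted p 1.53e-09. Translation factors did not pass as a list of 71 (median 0.07, camera adjusted p 0.543; median −0.19 with library size scaling, 0.02 without control 1 and 0.13 without control 2): Eif1 rose by 0.87 and Gspt1, Eif5b and Eif5a2 fell by 0.81, 0.68 and 0.61, with 2 up and 3 down adjusted over the list alone. Of 55 ribosome biogenesis genes Rrn3 fell by 0.70, with 0 adjusted over the list alone (median −0.14, camera adjusted p 0.0575, 0.368 with an estimated correlation). That list passed without control 3 (0.0265), without knockout 3 (0.0489), without a filter on low counts (0.0130), with library size scaling (0.00460) and with the length and GC trend removed (0.0457).

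Energy metabolism genes were higher as lists, with few single calls. Of 85 nuclear oxidative phosphorylation genes Uqcrfs1 and Cox7a2l rose by 0.72 and 0.91 on the log2 scale and Ndufs1 fell by 0.77, the same numbers adjusted over the list alone, and Atp5d had a log2 fold change of 0.71 that did not pass (median 0.23, camera adjusted p 0.000569, 0.600 with an estimated correlation). The median was −0.01 with library size scaling and 0.40 without control 2, and the call was lost without control 1 (median 0.05, 0.233) and with the length and GC trend removed (median 0.03, 0.983). Of 22 glycolysis genes Ldha, Ldhb and Tpi1 rose by 1.04, 1.11 and 1.13 and Hk2 and Pdk1 fell by 0.66 and 0.86, with 6 up and 3 down adjusted over the list alone (median 0.27, camera adjusted p 0.0406, 0.230 with an estimated correlation). That call was lost without control 1 (median 0.17, 0.0529) or control 2 (0.0961) without knockout 3 (0.170), without a filter on low counts (0.0531) and with library size scaling (median 0.02, 0.119). Of 13 mitochondrially encoded transcripts mt-Nd4l and mt-Nd5 rose, also 2 adjusted over the list alone, and mt-Co1 and mt-Nd1 had log2 fold changes of 0.98 and 0.72 that did not pass (median 0.37, camera adjusted p 0.00987, 0.405 with an estimated correlation). The median was 0.16 without control 1 and 0.98 without control 2, and the call was lost without control 3 (0.354) and with the length and GC trend removed (median 0.06, 0.701). For mt-Nd4l, the log2 fold change of 2.53 was 1.59 without knockout 3, where its call was lost (edgeR adjusted p 0.0767).

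Replication-dependent histone transcripts were higher as a list, with few single calls. Of 30 members, 12 of which had negative log2 fold changes, H2afx, Hist1h4d, Hist1h2ae, Hist1h2ab and Hist1h1b rose, with log2 fold changes of 1.61, 1.00, 1.14, 1.84 and 1.49, and 0 fell, while 5 rose and 2 fell adjusted over the list alone. The median was 0.58, with a camera adjusted p of 0.0365, and adjusted p = 0.405 with an estimated correlation. Most of these messages lack a poly(A) tail, which the oligo-dT primer needs, and near-identical copies share reads. The call was lost with the pair as 1 library (0.0926), without control 1 (median 0.37, 0.197) or control 3 (0.138), without knockout 1 or 2 (0.122 and 0.0784), without a filter on low counts (0.329) and with the length and GC trend removed (median 0.29, 0.428). Of 25 immediate early and dissociation response genes Dusp1 and Fos rose by 0.91 and 0.88, also 2 adjusted over the list alone, and Fosb had a log2 fold change of 0.60 that did not pass (median 0.17, −0.13 with library size scaling, where the call was lost at 0.257, camera adjusted p 0.0459, 0.444 with an estimated correlation). That call was lost with the pair as 1 library (0.0803), without control 2 or 3 (medians 0.02 and 0.06, 0.286 and 0.308), without knockout 1 or 2 (0.0642 and 0.0947), without a filter on low counts (0.0701) and with the trend removed (median 0.10, 0.151), and the median was 0.33 without control 1.

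**Figure D3:**
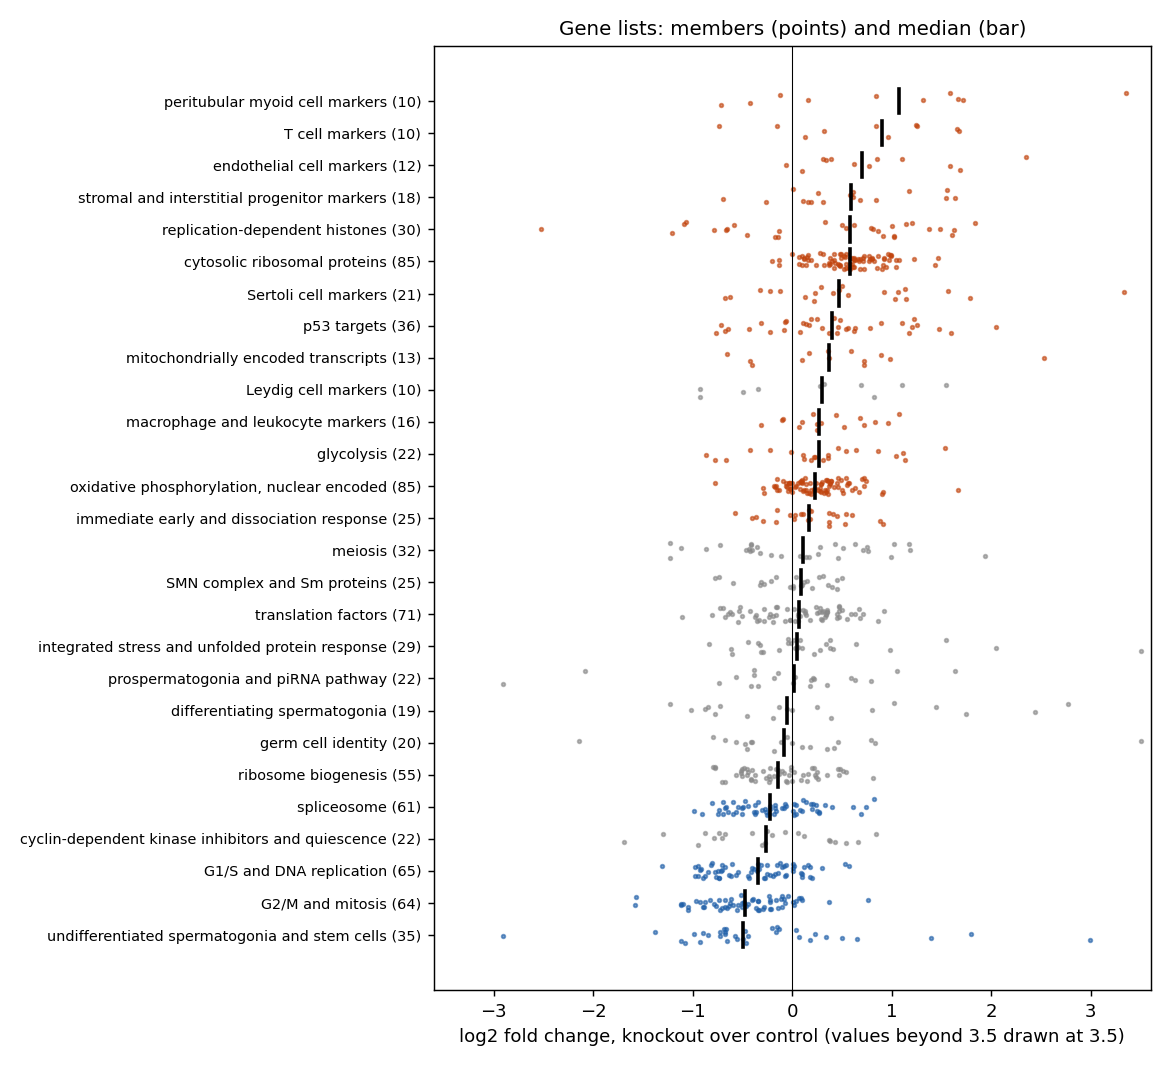
Log2 fold change of knockout over control (horizontal axis, TMM scaling) for the members of the 27 tested lists, with the number tested in brackets, points for genes and black bars for medians; lists called higher are orange, called lower blue and not called grey, and 2 values beyond 3.5 are drawn at 3.5. Medians run from −0.49 for undifferentiated spermatogonia to 1.08 for peritubular myoid cells (0.58 without knockout 3); with library size scaling the medians of 2 called lists, oxidative phosphorylation and immediate early genes, turn below 0.

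Markers of several somatic cell types of the testis were higher in the knockouts as lists. Not all members moved alike: 3 of 10 myoid, 2 of 18 stromal and 1 of 12 endothelial markers had negative log2 fold changes. Myh11, Pdgfra, Col1a1 and Cdh5, named after their values were seen, stood at 0.16, −0.26, 0.19 and −0.07 and did not pass. Of 21 Sertoli cell markers Clu, Inha, Cst12, Cldn11 and Defb19 rose and 0 fell, with 7 up adjusted over the list alone (median 0.47, camera adjusted p 0.000569, 0.131 with an estimated correlation). The median was 0.30 without control 2 and 0.73 without control 3. Cldn11 was near the floor, with 12 reads in all controls together and 121 in the knockouts. Clu rose from 30.6 ± 6.45 to 90.3 ± 14.9 CPM, a log2 fold change of 1.56 ± 0.20 (SE), and Inha, which encodes an inhibin subunit, from 9.49 ± 2.05 to 32.9 ± 4.91 CPM. Of the 21, 5 had negative log2 fold changes that did not pass, among them Trf, the most abundant, at 77.8 ± 6.73 and 66.7 ± 14.4 CPM, and Sox9 (−0.68), both named after their values were seen. Of 10 peritubular myoid markers Acta2, Myl9 and Actg2 rose, also 3 adjusted over the list alone, and Des had a log2 fold change of 0.84 that did not pass (median 1.08, camera adjusted p 0.000392, 0.158 with an estimated correlation). Without knockout 3 that median was 0.58. Acta2 stood at 60.8 ± 11.1 CPM in controls and 182 ± 39.2 CPM in knockouts. Of 18 stromal markers Ogn, Lum and Dcn rose by 1.55, 1.63 and 1.17, with 5 adjusted over the list alone, and Sfrp1 had 0.68 and did not pass (median 0.59, 0.34 without control 2, camera adjusted p 0.000200, 0.368 with an estimated correlation, 0.0778 by fry). Of 12 endothelial markers 0 were called by edgeR or adjusted over the list alone, with 4 higher at an unadjusted p under 0.05, 1 called by DESeq2 and 2 by limma-voom, yet the list passed (median 0.70, camera adjusted p 0.00871, 0.167 with an estimated correlation). Esam, Tie1, Emcn and Eng had log2 fold changes of 2.35, 1.59, 1.69 and 0.78 that did not pass. Their means in controls were low, at 1.89, 1.98, 3.17 and 5.74 CPM. The more abundant endothelial markers Egfl7 and Flt1, named after their values were seen, stood at 0.31 and 0.39 and did not pass. Each knockout library had more genes with a read at equal depth than any control, and the bearing of this on such low genes was not tested.

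Blood cell markers followed in part. Negative log2 fold changes were found in 3 of 16 macrophage and leukocyte markers and 2 of 10 T cell markers. Csf1r, Adgre1, Ptprc and Trac, named after their values were seen, stood at −0.09, 0.07, 0.10 and −0.16 and did not pass. Of 16 macrophage and leukocyte markers Laptm5 rose by 0.96, with 4 up adjusted over the list alone (median 0.27, camera adjusted p 0.00952, 0.405 with an estimated correlation), a list call lost without control 1 (0.0898) and without knockout 3 (0.0704), with medians of 0.45 without control 2 and 0.51 without control 3. Lyz2 stood at 657 ± 314 CPM in controls and 1384 ± 337 CPM in knockouts and did not pass, with C1qc and Tyrobp at log2 fold changes of 0.72 and 0.83. Of 10 T cell markers Trbc2, Cd3g and Lck rose by 1.65, 1.24 and 1.68, with 4 adjusted over the list alone, and Trbc1, which is nearly identical to Trbc2, had 0.96 and did not pass (median 0.90, camera adjusted p 0.00800, 0.167 with an estimated correlation). T cells carry THY1 as well. Of 10 Leydig cell markers 0 were called by edgeR, with 2 up adjusted over the list alone, 2 higher and 1 lower at an unadjusted p under 0.05, and 2 called by DESeq2 and by limma-voom (median 0.30, 0.11 without knockout 3, camera adjusted p 0.332). Fdx1, Cyp17a1, Nr5a1 and Cyp11a1 had log2 fold changes of 0.69, 1.55, −0.93 and 1.11, the last 2 being −0.60 and 0.60 without control 1 and Cyp11a1 2.13 without control 2. Erythroid markers, 4 of which were tested, were too few for camera: 0 were called by edgeR, 1 was lower at an unadjusted p under 0.05, DESeq2 and limma-voom called 1 each, and Hba-a1, Alas2, Hbb-bs and Hbb-bt had log2 fold changes of −2.12, 1.56, −1.84 and 1.59. Without control 1 the values of Alas2 and Hbb-bt were 2.57 and 1.04, and without control 3 those of Hbb-bs and Hbb-bt were −0.52 and 4.30.

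Of the 27 lists tested, 17 passed camera, 13 higher and 4 lower, and 14 of these 17 also passed with knockout 1 and 2 counted as 1 library. With an estimated correlation 0 of the 27 passed at the adjusted threshold, 7 had an unadjusted p under 0.05, and fry called 9.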

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

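The pair counted as 1 library and the removal of the length and GC trend were chosen after seeing the data; all other settings were fixed before the data were examined. The 713 genes (300 higher, 413 lower) became 1378 with library size alone, of which 1152 were lower, 1587 with DESeq2 (800 and 787), 2882 with limma-voom (1152 and 1730) and 0 (0 and 0) with the edgeR test against a log2 fold change of 1, where 499 genes had an unadjusted p under 0.05. With knockout 1 and 2 counted as 1 library, edgeR called 1 higher and 0 lower gene, with 1165 lower genes at an unadjusted p under 0.05. DESeq2 then called 466 genes, 263 of them lower, and limma-voom 505, 249 of them lower. Leaving out single libraries gave 3 to 839 genes, 2 to 414 higher and 1 to 468 lower. The low values came with each knockout left out (5, 10 and 3 genes), while leaving out control 1 or 3 gave 839 and 816. Each of these fits has 1 library fewer, so the number of libraries alone does not account for the low values. Why each knockout, and control 2 (182 genes), counts for more than the other controls was not tested. The other settings (DESeq2 size factors, 2 filters, no mitochondrial genes, length and GC trend removed) gave 643 to 959.

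Ddx20 was lower in all settings, with log2 fold changes of −2.05 to −1.61 when single libraries were left out. Its edgeR adjusted p lay above 0.05 with the pair as 1 library (log2 fold change −1.94, adjusted p 0.0541) and in the test against a fold change of 1 (−1.89, 0.345), as well as without knockout 1 or 3. Over all alternatives, DESeq2 and limma-voom included, the range was 4.41e-08 to 0.345, and the cause of the loss with the pair was not tested. The count of 17 lists was 0 with an estimated correlation and 9 with fry, and 12 to 16 with single libraries left out. Among called lists the estimate lay far above the preset value for ribosomal proteins (0.801), oxidative phosphorylation (0.594) and mitochondrially encoded transcripts (0.482). It lay below the preset value in others, such as G1/S (0.00896) and T cell markers (−0.0732). The camera adjusted p nevertheless went from 8.27e-09 to 0.0899 for G1/S and from 0.00800 to 0.167 for T cell markers. These values argue against a correlation above the preset value as the cause of the loss in those lists. What else differs between the forms of camera, and the cause of the losses with fry, was not tested. No list or named gene turned its direction past the threshold.

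The replicate numbers showed no pairing of the libraries: same-numbered deviations correlated at −0.0042, 0.0088 and 0.0065 over genes. Those with different numbers correlated at −0.016 to 0.0071. As no combination of a control and a knockout stood out, the check cannot exclude a pairing. With the replicate block 683 genes (312 higher, 371 lower) and 16 lists were called, and Ddx20 had a log2 fold change of −1.87. Among lists p53 alone lost its call (camera adjusted p 0.0634), and 13 named genes lost theirs. Not each sample correlated best with its own number. Depth limits low genes: a gene with 0 reads in the controls can have had up to 0.0957 CPM over the group, relative to total counts and for counting error only.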

Other observations

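Apart from the chance splits, the tests below were chosen after the results were seen. A list of 21 genes that respond to or restrain ERK signalling was chosen once the calls were known. By the edgeR test 5 fell and 0 rose: Pim1, Dusp9, Spred2, Spred1 and Etv5, with log2 fold changes of −1.64, −1.42, −1.20, −0.90 and −0.65. Others did not pass, among them Egr1, Etv4, Spry2, Spry4 and Ccnd1 (0.03, 0.04, −0.11, −0.05 and −0.02), Ier3 (0.53) and Spry1 (0.30). In all, 15 of the 21 had negative log2 fold changes. Fos and Dusp1, both called higher, were not put on this list. That list had a median of −0.15 and a camera adjusted p of 0.000938 over the 2 lists chosen this way (0.224 with an estimated correlation, 0.000775 with the pair as 1 library). Etv5, Lhx1, Egr4 and Bcl6b are also in the stem cell list, and as Pim1 and Etv5 were known calls when the list was made, its p is not independent evidence.

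In the other direction, 20 genes had 0 reads in all 3 controls and at least 1 CPM in each knockout library, the genes named here being chosen after their values were seen, and 0 genes the reverse; at equal depth each knockout library also had more genes with a read (18780 to 18972) than any control (16822 to 17860). The highest was Sult1e1, an estrogen sulfotransferase gene, at 4.56 to 6.26 CPM, which is at least 56.2-fold above the floor of 3 counts over the control group. Crisp2 was at least 33.9-fold higher. Reads in 202 olfactory receptor genes, which these cells are not known to use, were also counted. They stood at 75.6, 101 and 62.8 CPM in controls and 71.1, 86.8 and 75.9 CPM in knockouts. CPM and folds in this paragraph are relative to total counts, without TMM scaling. The TMM factors were 1.24, 0.956 and 1.10 in controls and 0.925, 0.928 and 0.891 in knockouts. Dividing by them would raise the values more in each knockout than in any control.

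Knockout 1 and knockout 2 may share cells or cDNA: their chi-square per gene of 1.779 lies far below the 11.956 of the next closest pair. No label names a shared animal, and near-identical animals or a shared preparation day stay open. In simulations with a shared draw the share of false calls rose, so part of the 713 genes may be due to it. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one with 713, and the highest other gave 0 (87 to 761 genes at an unadjusted p under 0.05). With 10 splits a share under 0.05 cannot be reached.

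The lower replication and mitosis transcripts may in part reflect fewer germ cells in the knockout samples, which stays open. In the test run first, the 20 germ cell identity genes (median log2 fold change −0.08) lay 0.32 above the 129 G1/S and G2/M genes (−0.40), with a 95% bootstrap interval over genes of −0.07 to 0.69 that holds 0 and so did not decide. The comparison was widened to 67 identity, piRNA and meiosis genes (median 0.03) only after that result was seen, and then gave 0.43 (0.11 to 0.66). With the length and GC trend removed the differences were 0.19 (−0.04 to 0.67) and 0.33 (0.10 to 0.61), and the meiosis median was −0.29 without knockout 3. As the intervals resample genes only and the wider set was picked after the narrower one had not decided, dilution is not excluded, for these genes or for the lower stem cell list, to which the comparison was not applied. The trend with gene length and GC content is argued against as the whole cause, since the G2/M median was −0.45 with the trend removed against −0.47 before, while a lower share of dividing spermatogonia was not tested. Of 10 splits 1, the real one, called as many lists, 17, and the highest other called 7, with 4 to 7 lists in splits that mix the genotypes. With 10 splits a share under 0.05 cannot be reached.

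The trend with length and GC content may account for part of the higher somatic markers: with it removed, 6 of 6 called cell type lists still passed, the leukocyte list at a camera adjusted p of 0.0489, while the Sertoli median went from 0.47 to 0.27 and the endothelial one from 0.70 to 0.80. Cst12, Cldn11, Defb19 and Lck lost their calls (edgeR adjusted p 0.0720, 0.0506, 0.103 and 0.0582), with log2 fold changes going from 1.13 to 0.78, 3.34 to 3.02, 1.15 to 0.82 and 1.68 to 1.56. In the main fit none of the 6 lists passed camera with an estimated correlation (adjusted p 0.131 to 0.405). A lower share of germ cells in the knockout samples, with the sort passing more other cells, stays open. If the sort passed all other types alike, their markers would rise by about the same amount. The medians of the 7 types were 0.27 to 1.08 (the highest 0.58 without knockout 3). They gave no difference by a permutation test over 97 markers (p = 0.453, two-sided), which does not show that they are equal. Types that the sort passes to differing degrees need not rise alike, so the permutation test cannot decide this. The erythroid markers, with 4 genes too few for this test, had a median of −0.14 (−2.42 to 0.43 when single libraries were left out, −1.88 with the pair as 1 library). The most abundant markers were Lyz2 (1384 ± 337 CPM in knockouts), Fcer1g (751 ± 112 CPM) and Dcn (655 ± 39.5 CPM). Which of these cell types a sort for THY1 would remove was not tested. Expression of such genes by the germ cells themselves cannot be told apart from carry-over in pooled cells.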
